A study of Mus musculus with 6 samples.

How the data were processed

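Lymph node cells of 7 pregnant mice, 4 Aire-DTR and 3 WT, were measured by droplet-based single-cell RNA sequencing. Per the labels, nodes were mashed and strained, lymphocytes were enriched on a Percoll gradient and stained, and live cells were sorted and tagged by hashtag antibodies so that mice and tissues could share a run. The sort is given as CD45+ CD3+ in the labels' protocol and as CD45+ in the series design, and 2849 of the cells were annotated as B cells. Per the labels, 160000 cells of each of pools 1 and 2 and 13200 cells of pool LN were split over 2 wells each, 6 wells in all. Uterine cells that pools 1 and 2 also held were not analysed here.

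The deposited matrix held UMI counts per cell and gene (9427 cells, 14125 genes, 29210327 UMIs). Per the submitters' processing notes, kallisto 0.46.1, bustools 0.40.0, Scanpy 1.7.0 and Seurat were used with genome build GRCm38. How each was used, how hashtags were assigned, how cells were filtered, whether doublets were removed and how cell types were named are not given in the sources used here. The deposited cell tables gave each cell's mouse, tissue, genotype, pregnancy phenotype and cell type, and a CD4 subset for 1101 cells. No further doublet removal was made: Cd79a UMIs occurred in 2.23% to 2.94% of cells of the CD4 and CD8 T cell types and Cd3 UMIs in 9.83% of B cells. The 5 files not used hold scaled values and their labels.

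Counts were summed per mouse and node over all CD4 T cells (CD4+ Naive T, CD4+ Mem T and CD4+ Treg) and over all CD8 T cells (CD8+ Naive T and CD8+ Mem T), where a sum had at least 20 cells. The udLN of WT mouse 97 had 9 CD4 T cells, and 14 CD8+ Naive T and 2 CD8+ Mem T cells. Both of its sums were left out, so gene tests in udLN compared 4 with 2 mice. Sums held 55 to 650 cells and 181985 to 2041421 UMIs for CD4, and 28 to 491 cells and 127889 to 1876934 UMIs for CD8 T cells. Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test in 1 fit of both nodes with pool as a term. This fit had no mouse term, so the 2 nodes of 1 mouse were treated as independent, which can affect the genotype p-values. Each node fitted alone, an alternative, avoids this. The node comparison and the interaction used mouse as a block. Benjamini-Hochberg adjusted p below 0.05 was the threshold. An SE given with an edgeR result is the size of the log2 difference over the square root of its F statistic. It rests on a spread moderated over genes or classes, so it can be smaller than the spread between mice implies. Gene lists, 27 in number, were fixed before the data were examined and tested with camera at a correlation of 0.01 where at least 3 members were measured, with the estimated correlation as an alternative. Log2 CPM per mouse used a prior count of 2.

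Shares of 9 cell classes among all cells and of 5 subsets among CD4 T cells were compared with edgeR's quasi-likelihood test on cell numbers with pool as a term, and by exact two-sided permutation of the mice (35 arrangements, smallest p 0.0571). The permutation doubled the 1-sided tail and moved mice across pools, so it did not keep the pool block. Intervals of single shares are 95% Wilson intervals. Pools were a block because, per the labels, their mice were loaded together. The correlation of deviations was 0.037 to 0.110 between mice of 1 pool and -0.083 to 0.039 between others in CD4 T cells of brLN, and 0.049 to 0.121 and -0.105 to 0.040 in CD8 T cells.

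Genes were named by a rule. In genotype comparisons these were the genes past the threshold on the same side in every pool, up to 10 in each direction, up to 4 past members of each list, and the 5 smallest p where fewer than 5 passed. In the node comparison they were up to 8 genes in each direction with log2 CPM above 5, and up to 3 list members. In the interaction they were the 5 smallest p. Aire, Foxp3, Cd44, Cd69, Ifng, Gzmb, Mki67, Il2ra, Ctla4 and Pdcd1 were always examined, and Il2 is not analysed here. Some items examined are not reported here. T cell receptor segments were counted and not named. Hbb-bs, Ly6c2 and Bcl2a1b share reads with near-identical copies, so their levels are uncertain. Coordinates are from GENCODE release 21 of the mouse series, matched by symbol.

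Scripts were tested on simulated data with 100 changed genes per fold. For the genotype comparisons, counts were drawn independently per sample, so recovery does not cover correlation between the nodes of 1 mouse. Each gene was drawn at the spread fitted for its level. Genes that vary more between mice are therefore not covered, and their recovery may be lower. At 2-fold and 4-fold, 53% and 91% were recovered for CD4 T cells of brLN, 40% and 70% for CD4 of udLN, 68% and 94% for CD8 of brLN, and 34% and 81% for CD8 of udLN. For the node comparison these were 64% and 96% (CD4) and 74% and 92% (CD8), and for the interaction 24% and 63% (CD4) and 25% and 68% (CD8). Alternatives changed the scaling, test, low-count filter, block, class definition, cell filter (at least 500 genes, under 10% mitochondrial UMIs and up to the 99th percentile of UMIs, 9221 cells), minimum cells (50 and 5), single cell types and each mouse in turn. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.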

Results

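Single cells from lymph nodes of 7 pregnant mice were compared between 2 genotypes. In Aire-DTR mice, diphtheria toxin removes cells that express Aire, the transcription factor through which thymic epithelium and some peripheral antigen-presenting cells display tissue antigens. WT mice given the same toxin were the controls. All dams had been mated to BALB/c males, so the fetuses carried paternal antigens foreign to the mother, and were given toxin for 9 days from the start of pregnancy. Nodes were taken at embryonic day 9.5. The question named by the submitters' title is whether activated T cells expand after depletion of Aire-expressing cells. There were 4 Aire-DTR mice (8, 36, 4 and 7) and 3 WT mice (6, 97 and 1). The deposited cell table records the pregnancy of Aire-DTR mouse 4 as resorbed and those of the other 3 Aire-DTR mice as IUGR. Each mouse gave uterine-draining lymph node (udLN) and brachial lymph node (brLN) cells, which makes 14 mouse-by-tissue samples. Brachial nodes lie outside the drainage of the uterus.

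The matrix held 9427 cells, 14125 genes and 29210327 UMIs (unique molecular identifiers, 1 per captured transcript). Cells had a median of 2878 UMIs (235 to 12050) and 1183 genes. Samples ranged from 48 cells and 155098 UMIs (udLN of WT mouse 97) to 1632 cells and 5149769 UMIs (brLN of Aire-DTR mouse 7). Median UMIs per cell were close between genotypes, at 2937 in Aire-DTR and 2883 in WT brLN and at 2792 and 2771 in udLN. Pool 1 (mice 8 and 6) gave 1009 cells, pool 2 (mice 36 and 97) 2249 cells and pool LN (mice 4, 7 and 1) 6169 cells, so each pool held both genotypes.

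Aire itself, on chromosome 10 (78030022 to 78043610, GRCm38), was almost undetected. It had 9 UMIs in 9 cells, of which 6 were in Aire-DTR brLN, 3 in WT brLN and 0 in udLN, and 5 of the 9 lay in B cells. At this depth the targeted gene could not check the genotype labels, since the cells sorted were lymphocytes and few would express it. The deposited annotation named 9 cell types: 2849 B cells, 2504 CD8+ Naive T, 2249 CD4+ Naive T, 692 CD4+ Mem T, 449 CD8+ Mem T, 425 CD4+ Treg, 98 gdT (gamma delta T), 92 Myeloid and 69 NK cells. Markers followed the names in part. Cd79a, a subunit of the B cell receptor, had a UMI in 98.3% of B cells (median 2245 UMIs per cell) and in 2.23% to 2.94% of cells in each of the 5 CD4 and CD8 T cell types (median 2460 to 4996 UMIs). Foxp3, the transcription factor of regulatory T cells, reached 423 CPM (counts scaled to library size) in CD4+ Treg against 5.16 CPM in CD4+ Naive T, but was also at 123 CPM in CD4+ Mem T. That class was mixed, with Cd8b1 at 234 CPM against 54.1 CPM in CD4+ Naive T. The chemokine gene Ccl5 reached 2993 CPM in CD8+ Mem T against 14.7 CPM in CD8+ Naive T. Hbb-bs, a beta globin gene, marked a difference between pools, with 2886 CPM in pool 1, 2152 CPM in pool 2 and 5.43 CPM in pool LN. Its level in Myeloid cells was 43975 CPM.

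CD4+ Mem T cells took a larger share of brachial node cells in Aire-DTR mice. They made up 7.94% ± 1.11 (SD, n = 4) of cells in Aire-DTR brLN against 4.73% ± 0.68 (SD, n = 3) in WT brLN, 1.77-fold in the edgeR fit. All 4 Aire-DTR mice (6.86% to 9.47%) lay above all 3 WT mice (4.31% to 5.51%). CD8+ Mem T cells made up 5.94% ± 0.61 (SD, n = 4) against 3.92% ± 0.28 (SD, n = 3), again with no overlap between genotypes. The CD4+ Treg class, at 4.12% ± 1.13 (SD, n = 4) against 3.71% ± 0.90 (SD, n = 3), was close between genotypes, but 151 of the 196 activated Treg cells of the CD4 subset table lie in the CD4+ Mem T class and 45 in CD4+ Treg. B cells made up 32.4% ± 3.7 (SD, n = 4) against 33.4% ± 8.0 (SD, n = 3). Gamma delta T cells, at 0.830% ± 0.416 (SD, n = 4) against 1.31% ± 0.51 (SD, n = 3), were lower in Aire-DTR mice in 3 of 3 pools.

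Of the 9 classes in brLN, 1 passed the test. The CD4+ Mem T share rose by a log2 difference of 0.82 (SE 0.25; edgeR's quasi-likelihood test on cell numbers with Benjamini-Hochberg adjustment, adjusted p = 0.0259), in 3 of 3 pools. Within pools, the Aire-DTR and WT shares were 7.93% and 5.51% in pool 1, and 9.47% and 4.31% in pool 2. In pool LN they were 7.50% and 6.86% against 4.37%. The exact two-sided permutation p was 0.0571 (35 arrangements, n = 4 against 3), which is the smallest that this permutation test can give. CD8+ Mem T did not pass (log2 difference 0.59, SE 0.26, edgeR adjusted p = 0.153; exact permutation p = 0.0571), nor did gamma delta T (edgeR adjusted p = 0.199) or CD4+ Treg (edgeR adjusted p = 0.995). The CD4+ Mem T call was lost with TMM scaling over classes (0.76, adjusted p = 0.117) and with limma on logit shares (0.82, adjusted p = 0.138), and also without any 1 of mice 1 (0.91, adjusted p = 0.0964), 36 (0.66, adjusted p = 0.0838), 4 (0.81, adjusted p = 0.107), 7 (0.86, adjusted p = 0.0833) or 97 (0.66, adjusted p = 0.0838). Pool 2 held only mice 36 and 97, and without 1 of them the pool term absorbs the other. The fits without mouse 36 and without mouse 97 are therefore the same fit. The CD4+ Mem T difference stayed positive in all 12 of its alternatives, not all of them separate fits, with adjusted p from 0.0260 to 0.138.

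**Figure D1:**
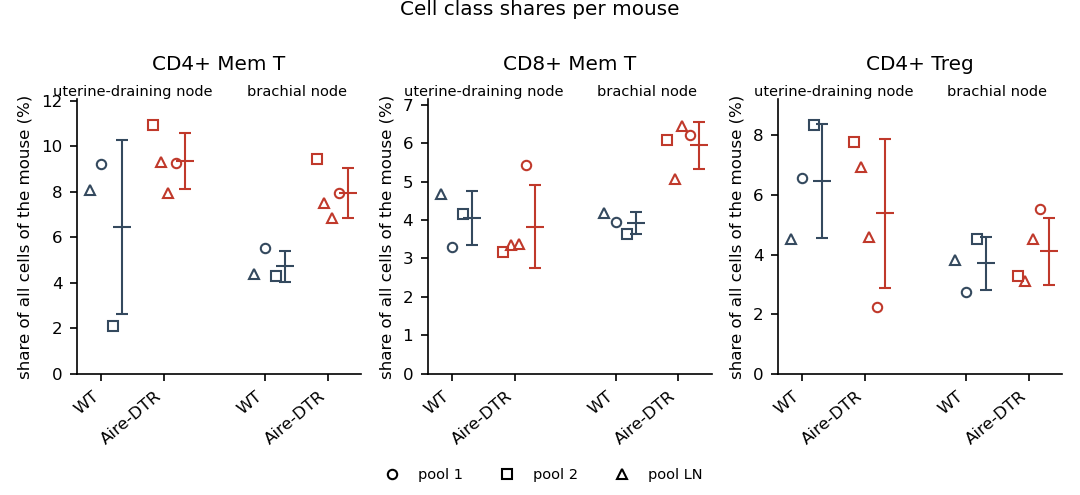
Share of all cells (%, y axis) that the deposited annotation called CD4+ Mem T, CD8+ Mem T or CD4+ Treg in uterine-draining (udLN) and brachial (brLN) nodes; each point is 1 mouse, its shape the pool, and bars are the mean ± SD of 4 Aire-DTR and 3 WT mice. In brLN the CD4+ Mem T shares of Aire-DTR mice (6.86% to 9.47%) lie above those of WT mice (4.31% to 5.51%).

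Within the uterine-draining nodes no class passed. CD4+ Mem T cells made up 9.37% ± 1.22 (SD, n = 4) in Aire-DTR and 6.45% ± 3.83 (SD, n = 3) in WT udLN (edgeR adjusted p = 0.780), and CD8+ Mem T cells 3.83% ± 1.07 (SD, n = 4) and 4.04% ± 0.70 (SD, n = 3). The WT spread came largely from mouse 97, whose udLN held 1 CD4+ Mem T cell among 48 cells (2.08%, 95% Wilson interval 0.369% to 10.9%); the other WT mice had 9.21% and 8.06%. edgeR called 0 of 9 classes in udLN, with 0 of 9 at an unadjusted p under 0.05. The genotype effect on CD4+ Mem T cells did not differ detectably between nodes (udLN minus brLN -0.45 on the log2 scale, SE 0.29, edgeR adjusted p = 0.357), so the larger share is not shown to belong to brachial nodes alone. Over both nodes of each mouse summed, an alternative chosen after the data were seen, CD4+ Mem T cells made up 8.49% ± 1.12 (SD, n = 4) against 5.59% ± 1.35 (SD, n = 3) of cells (edgeR adjusted p = 0.0377; exact permutation p = 0.0571, the smallest possible and not passing).

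Among CD4 T cells of the brachial nodes, follicular helper (Tfh) and Th17 cells had the higher shares in Aire-DTR mice. The deposited CD4 annotation split 1101 activated or regulatory cells into 347 Resting Treg, 244 Early Act. CD4, 196 Act. Treg, 173 Tfh and 141 Th17 cells. Tfh cells, which help B cells in germinal centres, made up 4.94% ± 1.70 (SD, n = 4) of CD4 T cells in Aire-DTR brLN and 1.85% ± 0.58 (SD, n = 3) in WT brLN, 2.23-fold in the edgeR fit. Th17 cells, the interleukin 17 lineage, made up 5.48% ± 1.05 (SD, n = 4) against 3.29% ± 0.70 (SD, n = 3), 1.76-fold in the edgeR fit, and Act. Treg cells 5.81% ± 1.80 (SD, n = 4) against 3.74% ± 0.85 (SD, n = 3). Resting Treg cells (10.3% ± 3.5, SD, n = 4, against 9.84% ± 3.04, SD, n = 3) and Early Act. CD4 cells (8.46% ± 0.55, SD, n = 4, against 8.14% ± 1.89, SD, n = 3) were close. The Tfh name fitted its genes, with Cxcr5 at 205 CPM, Pdcd1 at 243 CPM and the cytokine gene Il21 at 53.0 CPM, and Th17 cells had Tmem176b at 201 CPM. Act. Treg cells carried Foxp3 at 444 CPM and Ikzf2 at 835 CPM. Early Act. CD4 cells also held CD8 transcripts (Cd8b1 409 CPM, against 54.1 CPM in CD4+ Naive T and 1928 CPM in CD8+ Naive T).

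edgeR called 0 of the 5 subset shares in brLN, with 2 of 5 at an unadjusted p under 0.05, and limma on logit shares called 1. Tfh had a log2 difference of 1.16 (SE 0.42, edgeR adjusted p = 0.0683; exact permutation p = 0.0571), Th17 0.82 (SE 0.37, edgeR adjusted p = 0.110; exact permutation p = 0.0571) and Act. Treg 0.58 (SE 0.36, edgeR adjusted p = 0.212; exact permutation p = 0.171). Tfh, Th17 and Act. Treg shares were each higher in 3 of 3 pools. Tfh passed with the pool left out (edgeR adjusted p = 0.0485), with limma (adjusted p = 0.00866) and without mouse 7 (1.42, edgeR adjusted p = 0.0190), and Th17 passed without mouse 7 (0.98, edgeR adjusted p = 0.0420). In udLN the Tfh share was 8.47% ± 2.36 (SD, n = 4) against 3.79% ± 3.29 (SD, n = 3, edgeR adjusted p = 0.754), where WT mouse 97 had 0 of 9 CD4 T cells, which leaves a share of up to 29.9% open (95% Wilson interval).

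**Figure D2:**
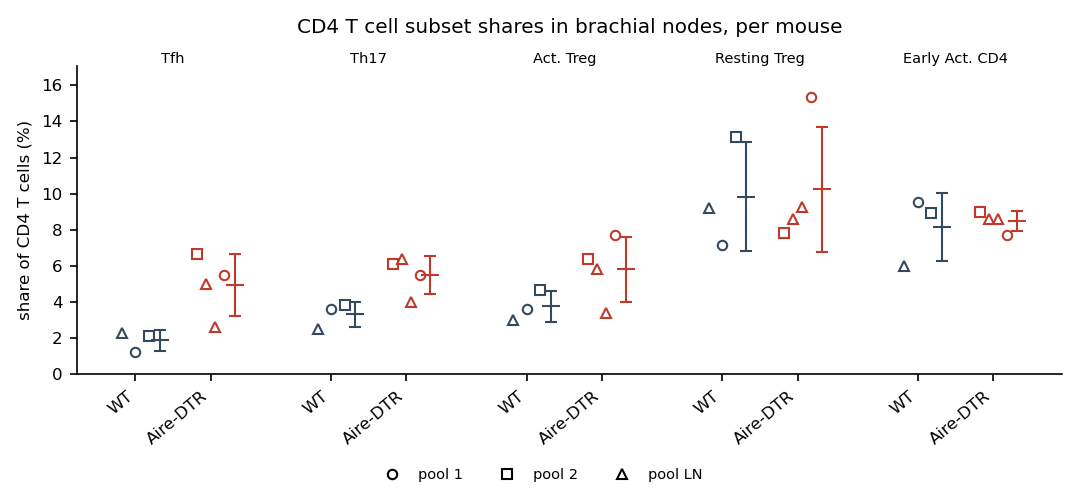
Share of CD4 T cells (%, y axis) in each of 5 deposited CD4 subsets (x axis) in brachial nodes; each point is 1 mouse, its shape the pool, and bars are the mean ± SD of 4 Aire-DTR and 3 WT mice. Tfh shares were 2.62% to 6.67% in Aire-DTR mice and 1.19% to 2.24% in WT mice.

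For genes, UMIs were summed per mouse over all CD4 T cells of a node and the 4 Aire-DTR sums were compared with the WT sums. In CD4 T cells of the brachial nodes, the Tfh and type 17 gene lists were higher in Aire-DTR mice. Of 11 measured Tfh genes, 10 were higher (median log2 fold change 0.23, camera adjusted p = 1.0e-04), and all 4 measured type 17 genes were (median 1.72, camera adjusted p = 1.0e-04). Neither call held with an estimated correlation (adjusted p = 0.222 for Tfh and adjusted p = 0.235 for type 17 with an estimated correlation). Maf, a transcription factor of Tfh and Th2 cells, was higher by 0.84 (SE 0.25). Il21 had 2, 5, 8 and 6 UMIs in the 4 Aire-DTR mice and 0 in each WT mouse, among 1126944, 731126 and 305350 UMIs. Tmem176b, a membrane protein gene expressed in type 17 cells, was higher by 2.67 (SE 0.72) and Ccr6, the receptor for the chemokine CCL20, by 1.95 (SE 0.60), each with all 4 Aire-DTR mice above all 3 WT mice. Ccr6 was not particular to Th17 cells, at 64.5 CPM there against 106 CPM in Act. Treg cells, whose share was also higher without passing, and 163 CPM in B cells. The Th2 list did not pass camera (adjusted p = 0.143), but 3 of its 6 genes passed when adjusted over the list alone, against 0 over all genes. These were Maf, the chemokine receptor Ccr4 (0.95, SE 0.37) and the cytokine Il4 (1.70, SE 0.69).

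Further lists moved in the same cells. Inhibitory receptors (7 of 8 higher, median 0.16, camera adjusted p = 0.0421), Treg genes (12 of 16 higher, median 0.16, camera adjusted p = 0.0226) and glycolysis genes (14 of 16 higher, median 0.11, camera adjusted p = 0.0226) were higher. Naive and quiescent genes were lower (16 of 18, median -0.07, camera adjusted p = 0.0226). None of these 4 calls held with an estimated correlation (adjusted p = 0.506 for Treg genes and adjusted p = 0.235 for each of the others with an estimated correlation). Il7r, the interleukin 7 receptor and a member of the naive list, went the other way, at 0.39 (SE 0.11), as did Foxp3 against the Treg list, at -0.43 (SE 0.20, edgeR adjusted p = 1.00). Adjusted over the list alone, the members that passed were 2 of 11 in the Tfh list (Maf and Il21), 2 of 4 in the type 17 list (Tmem176b and Ccr6), 1 of 18 in the naive list (Il7r), 1 of 16 in glycolysis (Pfkl, 0.74, a phosphofructokinase subunit) and 0 in the Treg and inhibitory receptor lists. Over all genes tested, 0 members of these lists passed. Leaving out 1 mouse ended the Tfh call without mouse 8 (camera adjusted p = 0.0529) and the type 17 call in no case. It ended the naive call without mouse 1 (0.188), 4 (0.158), 6 (0.0543) or 8 (0.0732), the Treg call without mouse 1 (0.695), 4 (0.124), 6 (0.256) or 8 (0.698), glycolysis without mouse 1 (0.585) or 4 (0.133) and inhibitory receptors without mouse 1 (0.144), 4 (0.178), 6 (0.566) or 8 (0.317). These CD4 sums include the larger CD4+ Mem T share. In CD4+ Mem T cells alone the Tfh (camera adjusted p = 0.0361) and type 17 (0.0240) calls stayed, while the Treg (0.724), inhibitory receptor (0.724), naive (0.359) and glycolysis (0.631) calls were lost. That class holds 160 of the 173 Tfh and 137 of the 141 Th17 cells, whose shares were higher without passing. A change within cells and a change of cell mix were therefore not separated. The Tfh call was lost in CD4+ Naive T (0.677) and in CD4+ Treg cells alone (0.282), as were the naive (0.965 and 0.887), Treg (0.677 and 0.130) and inhibitory receptor (0.677 and 0.0846) calls, the last 2 turned to lower in CD4+ Treg cells. The glycolysis call stayed in CD4+ Naive T cells and was lost in CD4+ Treg cells alone (0.887). The type 17 list has no value in either type alone. Without the pool term the naive (0.173), Treg (0.214), inhibitory receptor (0.214) and glycolysis (0.0994) calls were lost, and without the low-count filter the Treg (0.191) and inhibitory receptor (0.515) calls. With classes set by Cd4 and Cd8 UMIs the naive (0.121), inhibitory receptor (0.109) and glycolysis (0.121) calls were lost, and with each node fitted alone the inhibitory receptor call (0.0522). With the stricter cell filter, 3 of the 6 list calls stayed. Of the 34 fitted splits of the 7 mice, the real one included, 13 gave as many lists as the 6 seen here, the highest other 10, so chance is not excluded for their number.

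Gene by gene, little passed in CD4 T cells of the brachial nodes. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1 of 7702 genes, with 321 at an unadjusted p under 0.05 where chance gives 385, and DESeq2 called 0, with 106 unadjusted. The gene was Penk, the precursor of enkephalins (chromosome 4, 4133531 to 4138819), which fell by 3.46 (SE 0.61, edgeR adjusted p = 0.0112) and was lower in 2 of 3 pools. Its level rested on WT mouse 1, where 58 UMIs came from 2 cells, and without that mouse it did not pass (-5.33, edgeR adjusted p = 0.228). Of the 34 splits of the 7 mice that could be fitted, the real one included, 27 gave as many genes, the highest other 5, so chance is not excluded. The next genes by p did not pass: Rbm3, a cold-inducible RNA-binding protein, at 0.38 (SE 0.08, edgeR adjusted p = 0.0623), and the survival gene Bcl2a1b (0.81), the nuclear envelope gene Nrm (1.28) and the integrin gene Itgb1 (0.75), at an edgeR adjusted p = 0.597 each. Of the other genes named in advance none passed, with Cd44 at -0.07 (SE 0.27), Cd69 at -0.07 (SE 0.16), Il2ra at -0.08 (SE 0.20) and Ctla4 at 0.16 (SE 0.19). The inhibitory receptor Pdcd1 was at 0.40 (SE 0.28) and the granzyme Gzmb at -1.31 (SE 0.73). Ifng had 1 UMI in Aire-DTR and 0 in WT cells, and Mki67, a marker of dividing cells, 9 and 4 UMIs, too few to compare.

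In CD4 T cells of the uterine-draining nodes, the T cell activation list was lower in Aire-DTR mice, a call that passed in 7 of its 19 alternatives. The comparison had 4 Aire-DTR and 2 WT mice, because WT mouse 97 had 9 CD4 T cells there, under the minimum of 20. Of 26 measured activation genes, 18 were lower (median -0.19, camera adjusted p = 0.0367), a call that did not hold with an estimated correlation (adjusted p = 0.725 with an estimated correlation). The costimulatory receptors Tnfrsf9 (-1.36, SE 0.33; 2 of 2 pools) and Tnfrsf4 (-0.81, SE 0.23; 1 of 2 pools) and the chemokine Xcl1 fell when adjusted over the list alone (3 of 26, against 0 over all genes). Xcl1 had 0, 0, 2 and 1 UMIs in Aire-DTR mice 36, 4, 7 and 8 and 10 and 9 UMIs in WT mice 1 and 6. Oxidative phosphorylation genes were lower by a little (26 of 37, median -0.07, camera adjusted p = 0.0367, adjusted p = 0.725 with an estimated correlation), with 0 members past over all genes or over the list alone. Markers of B cells were higher (6 of 9, median 0.72, camera adjusted p = 0.0190, adjusted p = 0.725 with an estimated correlation), among them the class II gene H2-Aa (2.66, SE 0.66) and Cd79a (2.35, SE 0.87), the 2 of 9 past when adjusted over the list alone. The activation call was lost without mouse 1 (camera adjusted p = 0.599), 36 (0.306), 4 (0.131) or 97 (0.106). It was also lost without the low-count filter (0.295), without the pool term (0.179), with each node fitted alone (0.268), with the stricter cell filter (0.0740) and in CD4+ Naive T (0.806), CD4+ Mem T (0.554) or CD4+ Treg cells (0.280) alone. The oxidative phosphorylation call was lost without mouse 4 (0.131), 6 (0.802), 8 (0.486) or 97 (0.0550), without the pool term (0.179), with classes set by Cd4 and Cd8 UMIs (0.0599), with the stricter cell filter (0.0740), with a minimum of 5 cells (0.298) and in CD4+ Naive T (0.792), CD4+ Mem T (0.774) or CD4+ Treg cells (0.409) alone. The B cell marker call was lost without mouse 1 (0.549) or 7 (0.197), without the low-count filter (0.383) and with classes set by Cd4 and Cd8 UMIs (0.0694).

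edgeR called 2 of 7702 genes in these cells, with 545 at an unadjusted p under 0.05 (chance gives 385), and DESeq2 called 0, with 240 unadjusted. One was a T cell receptor segment, which was higher. The other was Gm20594, a predicted protein-coding gene (chromosome 6, 79817916 to 79818364), which fell by 0.60 (SE 0.12, edgeR adjusted p = 0.0325), with 4 of 4 Aire-DTR mice below both WT mice, in 2 of 2 pools. It did not pass without WT mouse 6 (-0.43, edgeR adjusted p = 0.488) or Aire-DTR mouse 8 (-0.49, edgeR adjusted p = 0.315), nor without the pool term (-0.63, edgeR adjusted p = 0.243). It turned to 0.02 (edgeR adjusted p = 1.00) with classes set by Cd4 and Cd8 UMIs and to 0.49 (edgeR adjusted p = 0.697) in CD4+ Treg cells alone, and passed in 12 of its 19 alternatives. Not passing were Hivep3 (-1.60, SE 0.35, edgeR adjusted p = 0.151), Capn7 (3.01, SE 0.70, edgeR adjusted p = 0.159), Tnfrsf9 (edgeR adjusted p = 0.245) and Xcl1 (edgeR adjusted p = 0.258). Il2ra (-0.60, SE 0.26), Cd44 (-0.40, SE 0.38), Pdcd1 (-0.26, SE 0.32), Ctla4 (-0.08, SE 0.23), Cd69 (-0.05, SE 0.23) and Foxp3 (0.03, SE 0.25) did not pass either.

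In CD8 T cells of the brachial nodes, effector genes were higher in Aire-DTR mice. Ccl5, a chemokine of memory and effector CD8 T cells (chromosome 11, 83525778 to 83530518), rose by 0.88 (SE 0.16, edgeR adjusted p = 0.00299). Mice varied more than this SE implies, at 9.40 ± 0.74 (SD, n = 4) against 8.82 ± 0.68 log2 CPM (SD, n = 3). The effector and cytotoxic list had 18 of 21 measured genes higher (median 0.24, camera adjusted p = 5.9e-07), which did not hold with an estimated correlation (adjusted p = 0.0899 with an estimated correlation). Of the 21, 5 rose when adjusted over the list alone, against 1 over all genes. These were Ccl5, the surface antigen Ly6c2 (0.36, SE 0.09), the interleukin 2 receptor chain Il2rb (0.59, SE 0.15), the chemokine receptor Cxcr3 (0.63, SE 0.20) and the transcription factor Tbx21 (1.53, SE 0.58). Cxcr3 and Tbx21 were also the 2 of 7 that rose in the Th1 list (6 of 7 higher, median 0.16, camera adjusted p = 0.0124, adjusted p = 0.295 with an estimated correlation), against 0 over all genes. Heat shock and immediate early genes, the dissociation list, were lower (14 of 23, median -0.10, camera adjusted p = 0.0128, adjusted p = 0.295 with an estimated correlation), with Hspa1a (-2.87, SE 0.84) the 1 of 23 past over the list alone and 0 over all genes. The Th1 call was lost without mouse 36 (camera adjusted p = 0.729) or 97 (0.544) and the dissociation call without mouse 36 (0.659), 6 (0.115), 7 (0.0504) or 97 (0.640). With classes set by Cd4 and Cd8 UMIs, 2 of the 3 list calls stayed. The effector call stayed without any 1 mouse but was lost in CD8+ Naive T (camera adjusted p = 0.243) and in CD8+ Mem T cells alone (0.611), and the CD8+ Mem T share in these nodes was 0.59 higher without passing (edgeR adjusted p = 0.153). Of the 34 fitted splits of the 7 mice, the real one included, 24 gave as many lists as the 3 seen here, the highest other 8, so chance is not excluded for their number.

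The other 2 genes past the threshold were Rbm3, which rose by 0.40 (SE 0.08, edgeR adjusted p = 0.0201; chromosome X, 8138975 to 8145880), and Igfbp4, an insulin-like growth factor binding protein of naive T cells, which fell by 0.49 (SE 0.10, edgeR adjusted p = 0.0310; chromosome 11, 99041244 to 99054392). All 4 Aire-DTR mice lay above all 3 WT mice for Rbm3 and below them for Igfbp4, in 3 of 3 pools. Rbm3 ranged from 712 to 880 CPM in Aire-DTR and from 547 to 695 CPM in WT mice, and Igfbp4 from 230 to 329 CPM and from 336 to 518 CPM. Ccl5 was higher in 2 of 3 pools: 1149 CPM (mouse 36) against 600 CPM (mouse 97) in pool 2, and 715 and 754 CPM (mice 4 and 7) against 259 CPM (mouse 1) in pool LN. In pool 1 it went the other way, 334 CPM (mouse 8) against 583 CPM (mouse 6). The naive list as a whole did not pass (camera adjusted p = 0.135), with 5 of 17 genes higher and 12 lower. Adjusted over the list alone, Il7r (0.41, SE 0.10) rose and Igfbp4 fell. Cd44 (0.39, SE 0.36), Cd69 (-0.17, SE 0.13) and Ctla4 (0.24, SE 0.71) did not pass.

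edgeR called these 3 of 7009 genes, with 297 at an unadjusted p under 0.05 (chance gives 350). DESeq2 called 0, with 105 unadjusted, and gave Ccl5 0.68 (SE 0.45). The edgeR fit without the pool term also called 0. With classes set by Cd4 and Cd8 UMIs, edgeR called 7 genes, and 0 of these 3 were among them. Ccl5 did not pass without mouse 1 (0.60, edgeR adjusted p = 0.207), 36 (0.85, 0.171) or 97 (0.91, 0.0640), Rbm3 without mouse 1 (0.38, 0.172), 36 (0.43, 0.171), 6 (0.39, 0.0570), 8 (0.37, 0.109) or 97 (0.44, 0.0727), and Igfbp4 without mouse 36 (-0.47, 0.314), 4 (-0.40, 0.122), 6 (-0.41, 0.348), 8 (-0.44, 0.246) or 97 (-0.45, 0.339). Over their 18 alternatives each, the adjusted p ran from 3.2e-19 to 1.00 for Ccl5 (10 past), from 0.00196 to 1.00 for Rbm3 (9 past) and from 4.4e-04 to 1.00 for Igfbp4 (7 past). The real split was among the 34 fitted splits of the 7 mice, of which 14 gave as many genes as the 3 seen here, the highest other 7, so chance is not excluded for their number.

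**Figure D3:**
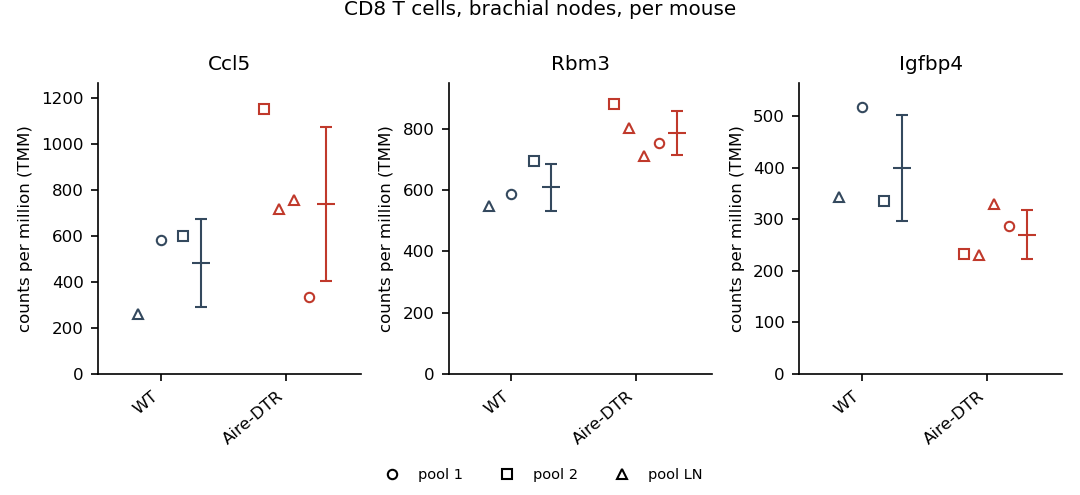
CPM (TMM-scaled counts, y axis) of Ccl5, Rbm3 and Igfbp4 in CD8 T cells of the brachial nodes; each point is 1 mouse, its shape the pool, and bars are the mean ± SD of 4 Aire-DTR and 3 WT mice. Rbm3 and Igfbp4 separate the genotypes (Rbm3 712 to 880 against 547 to 695 CPM), while Ccl5 of Aire-DTR mouse 8 (334 CPM) lies among the WT values.

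In CD8 T cells of the uterine-draining nodes, 2 genes rose. Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666), rose by 0.43 (SE 0.07, edgeR adjusted p = 0.00189) and Slc5a3, a myo-inositol transporter (chromosome 16, 92058322 to 92087473), by 2.81 (SE 0.59, edgeR adjusted p = 0.0342), both in 2 of 2 pools. Lars2 was at a high level, 4192.1 to 5502.5 CPM in Aire-DTR mice against 3249.3 and 4247.3 CPM in WT mice 1 and 6. Whether all these reads come from its mRNA was not tested. Slc5a3 rested on few UMIs, 6, 39, 28 and 16 in Aire-DTR mice 36, 4, 7 and 8 against 3 and 1 in WT mice 1 and 6. No list passed camera; the closest by member was the type I interferon response (camera adjusted p = 0.692), where 4 of 32 genes rose when adjusted over the list alone and 0 over all genes: Phf11b (1.36), Ifit1 (1.31), Trim30a (0.98) and Ifit2 (2.64). edgeR called 2 of 7009 genes, with 499 at an unadjusted p under 0.05 (chance gives 350), and DESeq2 called 0, with 252 unadjusted. The comparison had 4 Aire-DTR and 2 WT mice. With a minimum of 5 cells, which brings in WT mouse 97, 0 genes passed. Lars2 did not pass without WT mouse 1 (0.44, edgeR adjusted p = 0.172), without the pool term (0.39, edgeR adjusted p = 0.629) or with a minimum of 50 (0.43, edgeR adjusted p = 0.0739) or 5 cells (0.09, edgeR adjusted p = 0.926), and turned to -0.20 in CD8+ Mem T cells alone (edgeR adjusted p = 0.703). Slc5a3 did not pass without mouse 1 (2.59, edgeR adjusted p = 0.813), 6 (2.88, edgeR adjusted p = 0.0866), 7 (2.66, edgeR adjusted p = 0.120) or 8 (2.69, edgeR adjusted p = 0.174), nor without the pool term (2.78, edgeR adjusted p = 0.170), with classes set by Cd4 and Cd8 UMIs (1.65, edgeR adjusted p = 0.226), with the stricter cell filter (2.78, edgeR adjusted p = 0.0536), with a minimum of 50 (2.92, edgeR adjusted p = 0.0739) or 5 cells (2.58, edgeR adjusted p = 0.0916) or in CD8+ Mem T cells alone (1.23, edgeR adjusted p = 0.876), and passed in 7 of its 18 alternatives. Next by p and not passing were Polr3k (1.78), Ndufaf4 (1.45) and Sirt5 (1.06), at an edgeR adjusted p = 0.196 each. Cd69 (-0.40, SE 0.19), Ctla4 (-1.02, SE 0.80) and Cd44 (-0.13, SE 0.53) did not pass.

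**Figure D4:**
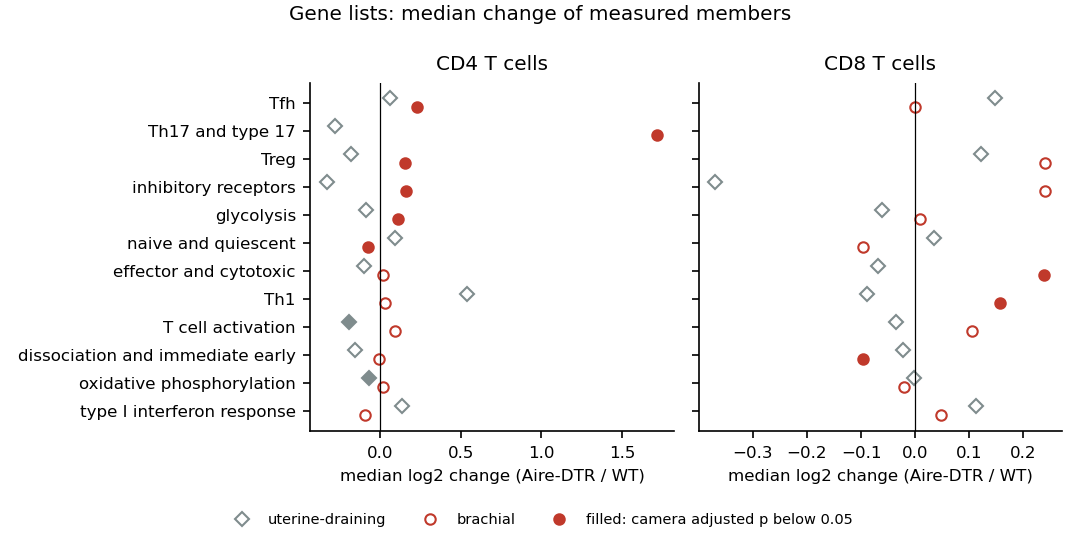
Median log2 fold change of Aire-DTR against WT (x axis, each panel with its own scale) for 12 gene lists (y axis) in CD4 (left) and CD8 T cells (right); diamonds are udLN, circles are brLN, and filled symbols have a camera adjusted p below 0.05 at a preset correlation. The type 17 list lies farthest out, at 1.72 in CD4 T cells of brLN.

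The globin gene Hbb-bs (chromosome 7, 103826534 to 103828096) passed over all genes in none of the 4 genotype comparisons. It was higher in Aire-DTR udLN (0.80, SE 0.28, in CD4 and 1.09, SE 0.28, in CD8 T cells) and lower in Aire-DTR brLN (-0.67, SE 0.18, and -0.63, SE 0.15). It was the 1 of 6 erythroid and platelet genes past when adjusted over the list alone in each comparison, and past over all genes in 0 of the 4 (edgeR adjusted p = 0.604, 0.196, 0.691 and 0.186).

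Uterine-draining and brachial nodes were compared within mice. In CD4 T cells of 6 mice, with mouse as a block, the uterine-draining node had more transcripts of some genes found in regulatory or anergic T cells. The sums cover all CD4 T cells, of which Act. Treg (log2 difference 0.83) and Tfh cells (0.94) took larger shares in udLN. A change within cells and a change of cell mix were therefore not separated. Izumo1r, the folate receptor 4 found on Treg and anergic cells (chromosome 9, 14885814 to 14903949), rose by 0.65 (SE 0.08, edgeR adjusted p = 1.3e-05) and the inhibitory receptor Lag3 (chromosome 6, 124904361 to 124911705) by 2.40 (SE 0.35, edgeR adjusted p = 1.6e-04), each in 6 of 6 mice. Foxp3 rose by 0.65 (SE 0.15, edgeR adjusted p = 0.0355; 5 of 6 mice; chromosome X, 7573644 to 7595245), the neuropilin Nrp1 by 1.25 (6 of 6), the follicle-homing receptor Cxcr5 by 1.30 (6 of 6) and Cxcr3 by 1.39 (5 of 6). S100a6, a calcium-binding protein of effector and memory cells (chromosome 3, 90612882 to 90624181), fell by 0.84 (SE 0.12, edgeR adjusted p = 7.4e-05), lower in udLN in all 6 mice.

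Of 7261 genes, 29 passed in this comparison, 19 higher and 10 lower in udLN, with 575 at an unadjusted p under 0.05 (chance gives 363). Also higher were Gadd45b (1.14), Art2b (1.06), Tbc1d4 (0.91), Bcl3 (0.78), Pou2f2 (0.75), the cytokine-signalling inhibitor Socs3 (0.75) and the integrin gene Itga4 (0.59). Also lower were Dapl1 (-0.62), Bzw2 (-0.47) and translation genes by a little: Rpl3 (-0.17), Rplp0 (-0.14), Rps2 (-0.13), Rps29 (-0.13) and Eef1a1 (-0.12). Hbb-bs passed at 0.83 but was higher in 3 of 6 mice only, and was at -0.011 with DESeq2. By list, anergy genes were higher (9 of 11, 3 past over all genes and 4 adjusted over the list alone, camera adjusted p = 1.1e-08), and this was the 1 list call that held with an estimated correlation (adjusted p = 0.0276 with an estimated correlation). Izumo1r, Nrp1 and Nt5e belong to both the anergy and Treg lists, and Lag3 to both the anergy and inhibitory receptor lists.

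Treg genes (13 of 16 higher, 3 past over all genes, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.2e-08), inhibitory receptors (5 of 8 higher, 1 and 4 past, camera adjusted p = 8.7e-05), Tfh genes (8 of 11 higher, 1 and 5 past, camera adjusted p = 0.00299) and Th1 genes (4 of 6 higher, 1 and 2 past, camera adjusted p = 0.00910) were higher too. With an estimated correlation these had adjusted p = 0.151 (Treg), adjusted p = 0.130 (inhibitory receptors), adjusted p = 0.262 (Tfh) and adjusted p = 0.151 (Th1). Among the members past over the list alone were the checkpoint receptors Tigit, Ctla4 and Pdcd1, the ecto-nucleotidase Nt5e, Maf and Stat4. B cell markers (camera adjusted p = 0.00980; 7 of 8 higher, 0 and 1 past; adjusted p = 0.668 with an estimated correlation) and the dissociation list (camera adjusted p = 0.0365; 16 of 23 higher, 1 and 4 past; adjusted p = 0.696 with an estimated correlation) were also higher in udLN. DESeq2 called 7 genes and the fit without the mouse block 7. Of the 32 splits that part every pair of nodes, 1 gave as many genes as the 29 seen, the real one, and the highest other gave 8. That is the smallest share 32 splits can give, which makes chance unlikely but does not exclude it. Izumo1r and S100a6 passed in each of their 10 alternatives, with adjusted p up to 0.00264 and 0.0190. Lag3 passed in 9, with adjusted p up to 0.00548, and with DESeq2 it had a log2 fold change of 2.51 but no adjusted p. Leaving out 1 mouse left 6 (without mouse 1) to 26 genes; Foxp3 passed in 3 of its 10 alternatives, with adjusted p from 0.00399 to 0.349. Of the 9 alternatives with an adjusted p, Cxcr5 passed in 3 (0.00219 to 0.444), Cxcr3 in 3 (0.00595 to 0.297) and Nrp1 in 7 (0.00201 to 0.0822). Cxcr5 did not pass without mouse 1 (adjusted p = 0.0516), 36 (0.444), 4 (0.0727), 6 (0.0680) or 7 (0.126), Cxcr3 without mouse 1 (0.0824), 36 (0.279), 4 (0.297), 7 (0.0649) or 8 (0.0819), and Nrp1 without mouse 1 (0.0822) or 8 (0.0557). Without the mouse block Cxcr5 (0.107) and Cxcr3 (0.114) did not pass.

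CD8 T cells of the uterine-draining node had more transcripts of the naive and quiescent list, a call that did not hold with an estimated correlation. The CD8+ Mem T share was lower there without passing (-0.46, edgeR adjusted p = 0.0768), and its part in this was not tested. Klf2, the transcription factor that drives exit from nodes (chromosome 8, 72319033 to 72321656), rose by 0.29 (SE 0.05, edgeR adjusted p = 0.00109; 6 of 6 mice) and Lef1 by 0.31 (SE 0.07, edgeR adjusted p = 0.0340; 5 of 6). Dtx1, a ubiquitin ligase of the Notch pathway that is linked to anergy (chromosome 5, 120680202 to 120711927), rose by 1.05 (SE 0.15, edgeR adjusted p = 6.1e-06; 5 of 6), and Acp5 by 0.44 (SE 0.07, edgeR adjusted p = 2.4e-04; 6 of 6). Adgre5 (0.50), Gimap6 (0.31) and Tagln2 (0.30) also rose. In all, 9 of 6971 genes passed, 8 higher and 1 lower, of which 2 were T cell receptor segments, with 388 at an unadjusted p under 0.05 (chance gives 349). Naive and quiescent genes (15 of 17 higher, 2 past over all genes and 2 adjusted over the list alone, camera adjusted p = 2.1e-05), TGF beta response genes (8 of 9 higher, 0 and 2 past, camera adjusted p = 0.00157) and dissociation genes (17 of 23 higher, 0 and 4 past, camera adjusted p = 0.00230) were higher, with adjusted p = 0.0956, adjusted p = 0.0969 and adjusted p = 0.0969 with an estimated correlation. Of the 32 splits that part every pair of nodes, only the real one gave as many genes as the 9 seen. The highest other gave 7, close to 9, so chance is not excluded. Dtx1 and Acp5 passed in each of their 10 alternatives; DESeq2 called 3 genes, the fit without the mouse block 2, and without mouse 8 there were 4 and without mouse 1 there were 15.

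The nodes also differed in cell types. The class annotated as Myeloid, in which 58.7% of cells had a Lyz2 UMI, 42.4% an Hbb-bs UMI and 44.6% a Cd3 UMI, took a larger share of udLN than of brLN (log2 difference 1.51, SE 0.32, edgeR adjusted p = 0.00275), and among CD4 T cells so did Tfh (0.94, SE 0.20, edgeR adjusted p = 9.96e-04) and Act. Treg cells (0.83, SE 0.22, edgeR adjusted p = 0.00449), while Early Act. CD4 cells took a smaller one (-0.54, SE 0.21, edgeR adjusted p = 0.0369). CD4+ Mem T (0.37, edgeR adjusted p = 0.0768), CD4+ Treg (0.55, edgeR adjusted p = 0.0877) and CD8+ Mem T (-0.46, edgeR adjusted p = 0.0768) did not pass.

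A few genes responded differently to genotype in the 2 nodes, by the test of the interaction in 6 mice. In CD4 T cells, Tnfrsf4, a costimulatory receptor also called OX40 (chromosome 4, 156013843 to 156016612), had a genotype effect lower by 1.75 in udLN than in brLN (-1.75, SE 0.27, edgeR adjusted p = 9.97e-04), and Gm20594 one lower by 0.68 (-0.68, SE 0.13, edgeR adjusted p = 0.0103). In CD8 T cells, the effect was larger in udLN for Lars2 (0.51, SE 0.09, edgeR adjusted p = 6.2e-05), Hbb-bs (1.46, SE 0.27, edgeR adjusted p = 2.8e-04) and Slc5a3 (3.28, SE 0.73, edgeR adjusted p = 0.0101). It was smaller in udLN for Ccl5 (-0.96, SE 0.17, edgeR adjusted p = 1.5e-04) and for the interferon-induced Ifi27l2a (-0.72, SE 0.14, edgeR adjusted p = 7.6e-04; chromosome 12, 103442167 to 103443680). edgeR called 4 of 7261 genes in CD4 and 7 of 6971 in CD8 T cells, 2 of them T cell receptor segments in each, with 440 and 418 at an unadjusted p under 0.05, and DESeq2 called 0 in both, with 63 and 70 unadjusted. Without WT mouse 1, which left 1 WT mouse with both nodes, Ccl5 turned to 0.56 (edgeR adjusted p = 0.860) and Tnfrsf4 was -0.73 (edgeR adjusted p = 0.906), Ifi27l2a (edgeR adjusted p = 0.770), Slc5a3 (edgeR adjusted p = 0.864) and Gm20594 (edgeR adjusted p = 0.124) did not pass. Without mouse 6, Lars2 (edgeR adjusted p = 0.202), Hbb-bs (edgeR adjusted p = 0.594) and Gm20594 (edgeR adjusted p = 0.537) did not pass, without mouse 8 Hbb-bs (edgeR adjusted p = 0.772), without mouse 4 Ifi27l2a (edgeR adjusted p = 0.266) and without mouse 36 Ccl5 (edgeR adjusted p = 0.0777).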

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

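Of the tests in this part, the free RNA test and the test within CD8+ Naive T cells were chosen only after the results were seen. Aire-DTR mouse 8 stood apart from the other 3 Aire-DTR mice in 5 of 72 groups examined with Dixon's ratio, where chance flags about 1 in 20 groups. Its udLN had a CD4+ Naive T share of 15.974%, below the others, and a CD8+ Mem T share of 5.4313%, above them. Its brLN had an NK share of 0%, 0 of 290 cells. In CD4 T cells of its brLN, Il2ra (7.2579 log2 CPM) and Pdcd1 (5.6274 log2 CPM) were above the others. The causes of these values were not tested.

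In CD8 T cells the genotype effect on Ccl5 was lower in udLN than in brLN by a log2 difference of -0.95921. In brLN, where Ccl5 was higher by 0.88 (SE 0.16), 2 explanations were tested. The CD8+ Mem T share of CD8 UMIs was 19.80% to 31.20% in Aire-DTR and 14.51% to 19.77% in WT mice. This share predicted a difference of 0.6734. Within CD8+ Mem T cells Ccl5 ran from 1318 to 3522 CPM in Aire-DTR and from 1687 to 3955 CPM in WT mice. There it was lower in Aire-DTR mice in pools 1 and 2 and higher in pool LN. A rise within memory cells was thus not seen in every pool. A change within cells and a larger share of memory cells still cannot be told apart. Free RNA is not a likely source, since Ccl5 in B cells was at 2.111% of its level in CD8 T cells.

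Rbm3 was higher in CD8 T cells of Aire-DTR brLN, by 0.40 (SE 0.08). Class composition is not the candidate explanation, because the difference within CD8+ Naive T cells alone was 0.412 (SE 0.083; edgeR adjusted p = 0.0194). Colder or longer handling of the Aire-DTR samples may contribute: Cirbp, the other cold-inducible RNA-binding protein gene, had a median log2 difference of 0.2914 over CD4 T, CD8 T and B cells of brLN, above the 0.2 set before that test. Cirbp passed in none of these 3 classes in either node, and in udLN, where Rbm3 was 0.35, 0.36 and 0.49, it was 0.17, 0.09 and 0.28 in CD4 T, CD8 T and B cells, so handling stays open. Handling times are not given in the sources used here, and no biological explanation other than genotype was tested.

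The other genotype effects that differed between nodes had untested causes. In CD4 T cells, Tnfrsf4 differed by -1.753 and Gm20594 by -0.67597. In CD8 T cells, Lars2 differed by 0.5085, Hbb-bs by 1.4593, Ifi27l2a by -0.71515 and Slc5a3 by 3.2752.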

How the results depend on the processing

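Single cell types, a minimum of 5 cells, T cells as the denominator and the splits of mice were chosen only after the results were seen. Alternatives that include uterine cells were not run. DESeq2 size factors in the edgeR fit left every count of calls as it was. Values below are numbers of genes, lists or shares past the threshold, and causes of the changes were not tested.

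With the DESeq2 Wald test, 0 genes passed in each genotype comparison and each interaction, 7 between nodes in CD4 and 3 in CD8 T cells, and Hbb-bs between nodes in CD4 turned to -0.011. Without the low-count filter there were 13 (CD4 udLN), 7 (CD4 brLN), 7 (CD8 udLN), 14 (CD8 brLN), 108 (CD4 between nodes) and 11 genes (CD4 interaction), and 1 list in CD4 udLN. With no replicate block (pool left out) there were 0 genes in each genotype comparison, 1 list in CD4 udLN, 2 lists in CD4 brLN and 1 subset share in brLN (Tfh, edgeR adjusted p = 0.0485). With the mouse block left out, there were 7 genes between nodes in CD4 and 2 in CD8; the block changed no other count by more than 1.5 times.

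With classes set by Cd4 and Cd8 UMIs there were 0 genes in CD4 udLN and in CD4 brLN, 11 in CD8 udLN, 7 in CD8 brLN, 3 lists in CD8 udLN, 6 lists in CD8 brLN and 0 class shares in brLN, and Gm20594 turned to 0.023. With the stricter cell filter there were 1 list in CD4 udLN, 3 lists in CD4 brLN and 1 gene in CD8 udLN. A minimum of 5 cells gave 6 genes in CD4 udLN and 0 in CD8 udLN, and a minimum of 50 gave 0 genes in CD8 udLN and 6 lists in CD8 brLN. Each node fitted alone gave 2 lists in CD8 udLN and 5 genes in CD8 brLN. With the estimated correlation 0 lists passed in CD4 udLN, CD4 brLN and CD8 brLN. Class shares in brLN fell to 0 with TMM over classes and 0 with limma on logit shares, where 1 subset share passed (Tfh).

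In CD4+ Naive T cells alone there were 0 lists in udLN, 3 genes and 2 lists in brLN. In CD4+ Mem T alone there were 0 genes and 1 list in udLN and 3 genes in brLN. In CD4+ Treg alone there were 0 genes in udLN, 3 genes and 2 lists in brLN. Gm20594 turned to 0.49, and the Treg list (camera adjusted p = 0.130) and inhibitory receptors (camera adjusted p = 0.0846) turned to lower. In CD8+ Naive T alone there were 4 genes in udLN. In CD8+ Mem T alone there were 1 list in udLN and 0 in brLN, and Lars2 turned to -0.20.

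Leaving out 1 mouse at a time, where a lone WT sample is assumed to vary like the other group, gave these ranges of genes: 1 to 4 (CD4 udLN), 0 to 4 (CD4 brLN), 1 to 4 (CD8 udLN), 0 to 9 (CD8 brLN), 6 to 26 (CD4 between nodes), 4 to 15 (CD8 between nodes), 1 to 11 (CD4 interaction) and 4 to 10 (CD8 interaction). Lists ranged from 1 to 4 (CD4 udLN), 2 to 11 (CD4 brLN), 0 to 1 (CD8 udLN) and 2 to 6 (CD8 brLN), class shares in brLN from 0 to 1 and subset shares in brLN from 0 to 2. Hbb-bs between nodes in CD4 ranged from -0.0038 to 1.17 and the interaction of Ccl5 in CD8 from -1.57 to 0.56. Labels of named genes did not require equal values. A gene called in the main fit was the same if still called in its direction, weaker if not called and reversed if its direction changed. A gene not called was the same within 1 SE, moved beyond it, and stronger if called in its direction. Of 516 values with a mouse left out, 336 were the same, 129 weaker, 42 moved, 7 stronger and 2 reversed. Of 597 under other settings, 439 were the same, 84 weaker, 57 moved, 13 stronger and 4 reversed.

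Splits of the 7 mice, the real one included, do not exclude chance for the genotype counts in brLN. Of 34 fitted splits, 27 gave as many genes as the 1 in CD4 (highest other 5), 14 as many as the 3 in CD8 (highest other 7), 13 as many lists as the 6 in CD4 (highest other 10) and 24 as many as the 3 in CD8 (highest other 8). The split of pools 1 and 2 against pool LN could not be fitted with pool as a term. Between nodes, 1 of 32 splits, the real one, gave as many as the 29 genes in CD4 (highest other 8). In CD8, 1 of 32 gave as many as the 9 (highest other 7). That is the smallest share 32 splits can give, so chance is less likely but not excluded.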

Other observations

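Rbm3, a cold-inducible RNA-binding protein gene, was higher in Aire-DTR mice in CD4 T, CD8 T and B cells of both nodes. It passed only in CD8 T cells of brLN (edgeR adjusted p = 0.0201). It did not pass in CD4 T cells (0.0623) or B cells of brLN, nor in udLN (0.458 in CD4 T, 0.413 in CD8 T and 0.193 in B cells). In B cells the log2 difference was 0.37 (SE 0.09) in brLN and 0.49 (SE 0.10) in udLN, and in udLN it was 0.35 in CD4 and 0.36 in CD8 T cells. In B cells edgeR called 0 of 5779 genes in either node, with 168 at an unadjusted p under 0.05 in brLN and 342 in udLN.

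Of the tests in this part, the share among T cells was chosen only after the result was seen. The larger CD4+ Mem T share in Aire-DTR brachial nodes (log2 difference 0.82, SE 0.25) was weighed against 3 explanations. The share of B cells in the denominator is unlikely, since among T cells the difference was 0.8457. Depth per cell was tested only weakly. The window of 1500 to 6000 UMIs kept most brLN cells, and among its 5760 cells the difference was 0.8123. CD4+ Mem T cells with a Cd8a or Cd8b1 UMI are an unlikely source, since without those 85 cells it was 0.8365.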
